A study of Zea mays with 18 samples.

How the data were processed

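MicroRNA (miRNA) levels were measured in the leaf of rank 4 of maize seedlings (Zea mays, hybrid ADA313). Per the labels, the design had 18 arrays in 6 groups of 3 biological replicates. The groups were control and chilled seedlings, each in 3 zones of leaf 4: the meristem, the elongation zone and the mature zone. Control seedlings grew at 25 °C by day and 20 °C at night, with 16 h of day and 8 h of night, 15000 lux and 70% relative humidity. Chilled seedlings had nights at 4 °C, with the other conditions as in the controls. The labels do not say how long the chilling lasted, how a zone was cut, whether a replicate pooled several seedlings or whether the zones of one replicate number came from the same seedlings. RNA was extracted with Trizol, and 10 µg per sample was tailed and ligated to biotin with the FlashTag HSR kit, per the labels' protocols. Affymetrix Expression Console is the tool named in the submitters' processing notes. Its version, the background correction, the normalization between arrays and the summarization are not given in the sources used here.

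The table analysed holds no value of a single array. For each maize miRNA probe set the authors deposited 6 averages in log2 units, each a bi-weight average signal over the arrays of one group, per the file headers. The bi-weight average is a mean that gives less weight to distant values. The authors also deposited the p-value of an ANOVA over all 6 conditions and an FDR p-value, per the file headers. The ANOVA p-values ran from 2.03e-13 to 0.040982 in the authors' deposited table, so the table holds only probe sets under some p limit, and every count refers to this preselected set. The FDR p-values in the authors' deposited table reached 0.075676, and 204 probe sets had one under 0.05. The table lists 228 maize probe sets from 28 families, 96 named as a 5p arm, 115 as a 3p arm and 17 without an arm. Of these, 119 share all their values with another probe set, up to 11 together, which leaves 147 distinct profiles; near-identical family members cannot be told apart by this array and are named together. The names give 157 miRNA genes, of which 150 matched a gene of the RefSeq annotation of Zm-B73-REFERENCE-NAM-5.0. No genome build is given for the table, so no coordinates are printed.

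The planned analysis was a limma fit over the 18 single arrays. It could not be made from group averages. The residual SD of each miRNA was instead recovered from the authors' deposited ANOVA p-value. That p was turned back into F with 5 and 12 degrees of freedom, and the variance between the 6 averages, with 3 arrays per group, was divided by F. Recovered variances were moderated with squeezeVar of limma (prior degrees of freedom 1.945, total 13.94). Each contrast between averages was then tested with a two-sided moderated test. P-values were adjusted by the Benjamini-Hochberg method over the 228 probe sets within a contrast, with a threshold of 0.05. Every adjusted p in the text comes from this limma test unless another source is named, and every SE is the recovered SE of a difference. The differences between zones in the chilling effect were tested by the moderated F test over both interaction contrasts and by the 3 pairwise interaction contrasts. This way assumes an ordinary ANOVA with equal spread in the groups and takes a bi-weight average for a mean. In the authors' deposited table the 198 p-values of 1e-06 or more are rounded to 6 decimals, which is coarse for the smallest of these, the other 30 have up to 3 significant digits, and the model behind them is not stated. Because the table was preselected on the same ANOVA, the adjusted p-values of the contrasts do not strictly hold the false discovery rate. How many arrays showed each direction cannot be given. P-values measure the spread between the arrays, which the labels call biological replicates. Arrays give no read depth, and their number limits the precision.

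The recovery was tested on simulated data for chilling against control in 1 zone, with 3000 simulated miRNAs, of which 2542 passed the p limit with normal noise. Changes of 1, 2 and 3 log2 units were called in 48.4%, 82.7% and 94.9% of cases, against 47.3%, 80.6% and 94.9% with the simulated single arrays. The share of false calls was 10.1%, against 6.49% with single arrays, so it lay above the nominal rate. The ratio of the recovered SD to the SD fitted on the simulated single arrays had a median of 1.01, with 0.884 at the 5th and 1.19 at the 95th percentile. The recovered SD was not compared with the SD used to simulate. With heavy-tailed noise and 2566 miRNAs kept, the shares called were 58.8%, 87.8% and 98.0%, with 8.81% false calls. The simulation used the ordinary ANOVA with equal spread that the recovery assumes. Its noise was independent for each miRNA, and its p-values were less coarsely rounded than many deposited ones. It therefore tests the recovery where these assumptions hold, and not the assumptions themselves.

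Before the data were examined, 7 lists of miRNA families were fixed. These were auxin (miR160, miR164, miR167, miR390, miR393), growth and leaf development (miR156, miR159, miR166, miR171, miR172, miR319, miR396, miR529), and copper, laccase and oxidative stress (miR397, miR398, miR408, miR528). The others were sulfate and phosphate supply (miR395, miR399, miR827), small RNA machinery (miR162, miR168), stress transcription factors and F-box (miR169, miR394), and triggers of phased small RNAs (miR482, miR2118, miR2275). Each family with at least 3 distinct profiles was a further list, which gave 16 family lists. Lists and families hold whichever arms the table names, and the 6 probe sets of miR160 are all 3p arms. A target named for a family need not be a target of the arm measured. List members were counted past the threshold over all probe sets and adjusted over the list alone. These counts are of probe sets, so members with identical values count separately. Lists were tested against the other miRNAs with cameraPR of limma on the distinct profiles, with Benjamini-Hochberg adjustment over the 23 lists within a contrast. The correlation within lists was to be estimated from the arrays. This needs single arrays, so it was preset to 0.01, and 0.1 was tried as an alternative; which list calls hold with an estimated correlation is not known. The families miR156, miR166, miR319 and miR396 and the calls between control zones served as markers of neighbouring zones, and miR2118 and miR2275 as markers of reproductive organs.

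The rule for named miRNAs was also fixed before the data were examined. In each chilling contrast and each control zone contrast, it takes the 12 highest and 12 lowest differences among miRNAs past the threshold whose 3 arrays of one group lie beyond all 3 of the other. Where fewer than 10 qualify, the miRNAs with the smallest p fill up to 10 and are described as not passing. For the interaction it takes the 10 smallest p, and for each list 2 to 4 members with the smallest p. The part on single arrays could not be applied. Of the miRNAs taken by the rule, the text prints those that matter in full and summarises the rest. A log2 level of 2 was taken as the background after the data were seen; a difference from a group at this level is measured against background, not against a known amount. The alternatives fixed before the data were examined that could be computed were leaving out the 25% of probe sets with the lowest mean, quantile normalization and median subtraction of the group averages, a trended robust prior, an unadjusted p with a 2-fold minimum, joint adjustment over contrasts, and 1 probe set per identical profile. Alternatives added after the data were seen were an ordinary test without moderation, a Tukey range test, an ANOVA p read with 16 residual degrees of freedom, a recovered SD enlarged by a factor of 1.25, leaving out miRNAs under the background level in every group, and the correlation of 0.1. Median subtraction used medians over probe sets, in which identical probe sets count separately, and moved all differences of a contrast by the same amount. Over distinct profiles the medians of the control and chilled mature zone were close (1.68 and 1.55), and subtracting these was not tried. Median subtraction moved the chilling differences by 2.41 in the mature zone, by 0.85 on average, by 0.14 in the meristem and by 0.02 in the elongation zone. It moved the control zone differences by 0.13 (elongation zone against meristem), 1.29 (mature against elongation zone) and 1.42 (mature zone against meristem). Quantile normalization does not move all differences of a contrast by the same amount. Its median shift over probe sets was -0.20, 0.77 and 0.54 for these 3 contrasts, and at most 0.07 in size for the chilling contrasts. Single differences could move by more. The analysis ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.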

Results

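The levels of maize miRNAs were compared between seedlings with warm nights and seedlings with chilled nights, in the meristem, the elongation zone and the mature zone of leaf 4. These zones are successive stages of leaf growth, and the leaf was used as a model of how chilling acts on growth. Each of the 6 groups was represented by 3 arrays, for which the authors' average log2 signal was analysed. The averages of the 228 miRNA probe sets, which form 147 distinct profiles, ran from 0.59 to 12.65. The median over probe sets was 6.0 in the control meristem, 5.87 in the control elongation zone and 4.59 in the control mature zone. In chilled leaves it was 5.87, 5.85 and 2.18 in the same order. Over the distinct profiles, where identical probe sets count once, the median was 3.33, 3.44 and 1.68 in the control zones and 3.23, 3.78 and 1.55 in the chilled zones. Between 48 and 91 of the 147 profiles lay under the background level of log2 2 in a group, with 58, 54 and 85 in the control zones and 59, 48 and 91 in the chilled zones. The recovered SD within groups had a median of 0.34 log2 units over the profiles, with quartiles of 0.21 and 0.61 and a range from 0.07 to 1.84. The differences given for single miRNAs are on the log2 scale, each with its recovered SE and its adjusted p.

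Control leaves were compared along the zones first, to show how miRNAs change between dividing, expanding and mature tissue. From the meristem to the elongation zone, miR396c and miR396d, which share 1 profile and belong to a family that targets growth-regulating factors, rose from 3.70 to 11.31 (difference 7.61, SE 0.59, adjusted p = 2.86e-07). Of the miR167 family, which targets auxin response factors, 14 of 17 members (5 of 8 distinct profiles) rose and 3 members did not pass, though as a family it did not stand apart by cameraPR (adjusted p = 0.0571). Its miR167e to miR167j 5p profile rose from 7.50 to 10.45 (2.95, SE 0.33, adjusted p = 8.63e-06), and its miR167a to miR167d 5p profile from 7.62 to 10.78 (3.16, SE 0.52, adjusted p = 0.000276). In the other direction, the miR319a/b/c/d-3p profile, whose family targets TCP transcription factors, fell from 10.47 to 5.59 (-4.88, SE 0.73, adjusted p = 0.000117). The miR166n-5p level fell from 10.66 to 6.91 (-3.75, SE 0.26, adjusted p = 1.84e-07), and miR172e, of a family that targets AP2-type factors, from 11.01 to 8.70 (-2.31, SE 0.30, adjusted p = 4.55e-05).

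In all, 106 of 228 probe sets passed the threshold between the elongation zone and the meristem of control leaves, 80 higher and 26 lower in the elongation zone. With quantile normalization the split was 44 higher and 47 lower. Of the auxin list, 28 of 44 members rose, 4 fell and 12 did not pass, and adjusted over the list alone 28 rose and 5 fell. Of the growth list, 24 of 99 rose, 19 fell and 56 did not pass, with 23 and 19 adjusted over the list alone. Of the sulfate and phosphate list, 20 of 34 rose and 14 did not pass, with 20 risers adjusted over the list alone. Counted as distinct profiles, 14 of 27 auxin profiles rose and 3 fell, 11 of 60 growth profiles rose and 12 fell, and 6 of 20 sulfate and phosphate profiles rose. Of the copper list, 3 of 10 rose, with 3 adjusted over the list alone: miR408b-5p (3.11) and the profile shared by miR408a and miR408b-3p, which rose from 3.92 to 7.96 (4.04, SE 0.68, adjusted p = 0.000298). Of the stress factor list, 3 of 21 rose and 2 fell, against 0 and 2 adjusted over the list alone. Of the phased small RNA triggers, 2 of 15 rose, against 0 adjusted over the list alone, and of the 4 small RNA machinery members none passed under limma, adjusted over the list alone or at an unadjusted p under 0.05. No fixed list stood apart from the other miRNAs by cameraPR, and the miR166 family, mostly 5p arms, did, as lower in the elongation zone (adjusted p = 0.00255, and 0.131 with the correlation of 0.1).

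Between the elongation and the mature zone of control leaves 96 of the 113 probe sets past the threshold were lower in mature tissue, a majority that was lost with quantile normalization (32 of 72) and median subtraction (25 of 136). The miR167d-3p level fell from 7.82 to 0.99 (-6.83, SE 0.65, adjusted p = 1.62e-06), miR171d/e-5p from 7.06 to 1.31 (-5.75, SE 1.40, adjusted p = 0.00527) and miR394a/b-5p, whose family targets an F-box gene, from 5.87 to 1.44 (-4.43, SE 0.96, adjusted p = 0.00262). The mature levels of these 3 profiles are at background. The 5p arm of miR166 fell in several members, such as miR166n-5p from 6.91 to 1.72 (-5.19, SE 0.26) and miR166b/d-5p from 10.91 to 6.79 (-4.12). The miR167e to miR167j 5p profile rose further, from 10.45 to 11.49 (1.04, adjusted p = 0.0193).

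The other 17 probe sets were higher in the mature zone, and 21 of the 79 profiles past the threshold were at background in both zones. The split was 40 higher and 32 lower with quantile normalization and 111 higher and 25 lower with median subtraction. Of the stress factor list, 17 of 21 members fell and 4 did not pass, and of the 4 small RNA machinery members all 4 fell. With quantile normalization 10 of the 17 stress factor falls were above 0, among them miR169d and miR169m/n/q-5p, and so were miR162-3p, miR162-5p and miR168a-3p of the small RNA machinery. With median subtraction 4 of the 17 and miR162-3p were above 0. Of the growth list, 47 of 99 fell and 5 rose, and of the auxin list 15 of 44 fell and 8 rose. The sulfate and phosphate list had 7 of 34 lower and 1 higher, the copper list 3 of 10 lower, and the phased small RNA triggers 3 of 15 higher and 2 lower. The counts of all 7 lists were the same when adjusted over the list alone. Of the falls, 9 of the 47 growth members and 1 of the 7 sulfate and phosphate members were no longer below 0 with quantile normalization. With median subtraction 12 of 47 growth, 4 of 15 auxin, 4 of 7 sulfate and phosphate, 3 of 3 copper and 1 of 2 trigger falls were above 0. No rise turned under either scaling. The only list to stand apart by cameraPR was the miR166 family, mostly 5p arms, as lower (adjusted p = 0.000489, and 0.0528 with the correlation of 0.1).

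Across the whole span from meristem to mature zone in control leaves, miR396c/d rose from 3.70 to 11.80 (8.10, adjusted p = 4.77e-08) and the miR167e to miR167j 5p profile by 3.99 (SE 0.33, adjusted p = 1.75e-07). The miR166n-5p level fell from 10.66 to 1.72 (-8.94, SE 0.26, adjusted p = 1.42e-12), which is at background in the mature zone. In the authors' deposited table miR166n-5p had the smallest ANOVA p of all, 2.03e-13. The threshold was passed by 133 probe sets, 44 higher and 89 lower in the mature zone, against 77 and 73 with quantile normalization and 145 and 40 with median subtraction. Of the growth list, 55 of 99 fell and 11 rose, against 55 and 13 adjusted over the list alone. Of the auxin list 13 of 44 fell and 15 rose, of the sulfate and phosphate list 3 of 34 fell and 13 rose, of the stress factors 11 of 21 fell, of the small RNA machinery 3 of 4 fell and of the copper list 3 of 10 rose. These counts were the same adjusted over the list alone, while the phased small RNA triggers had 2 of 15 higher and 3 lower, against 1 and 2 adjusted over the list alone. With quantile normalization 4 of the 55 growth falls, 4 of the 11 stress factor falls (miR169d and miR169m/n/q-5p) and miR162-5p of the small RNA machinery were no longer below 0. With median subtraction 14 of 55 growth, 3 of 13 auxin, 2 of 3 sulfate and phosphate, 4 of 11 stress factor and 3 of 3 trigger falls were above 0, as was miR168a-3p of the small RNA machinery. By cameraPR the miR166 family, mostly 5p arms, stood apart as lower (adjusted p = 0.000217, and 0.0337 with the correlation of 0.1), and the miR160 family too (adjusted p = 0.0481, and 0.148 with the correlation of 0.1 or 0.114 with quantile normalization).

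**Figure D1:**
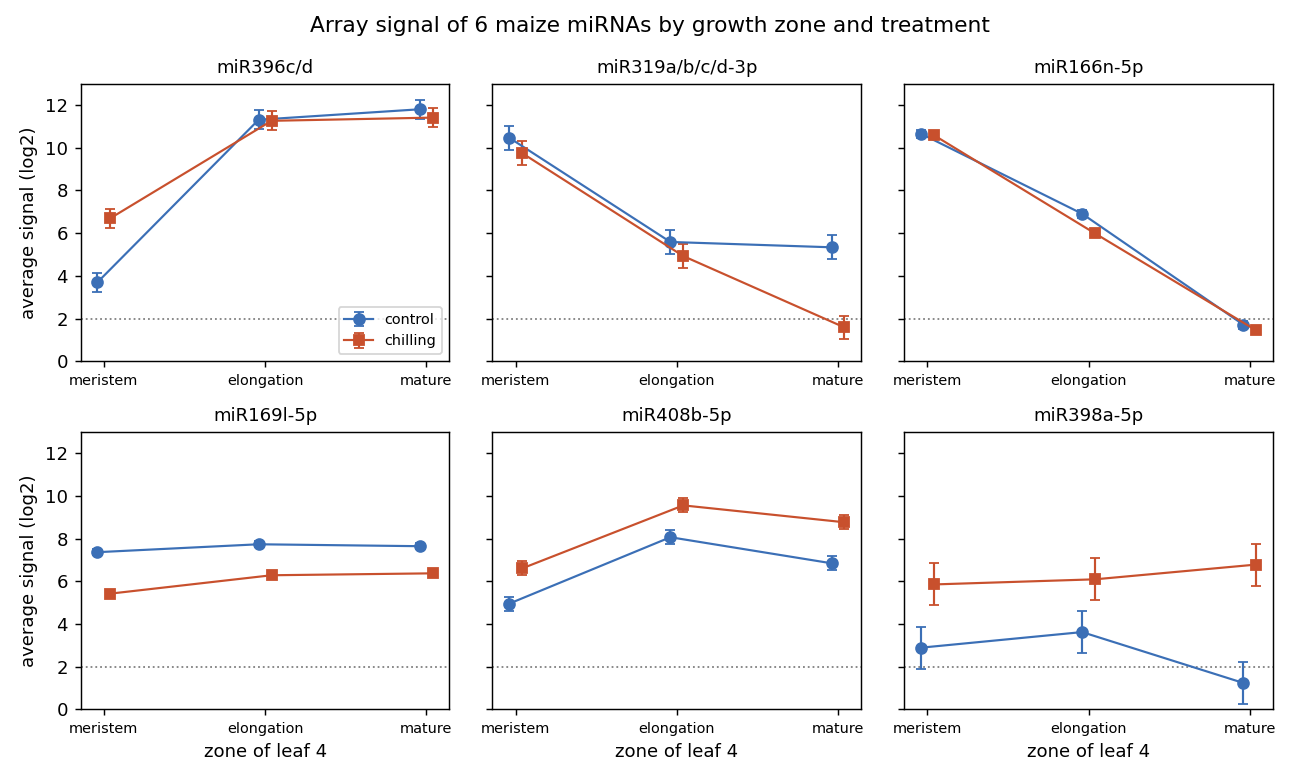
Average log2 array signal of 6 miRNA profiles in the meristem, elongation zone and mature zone of control (blue circles) and chilled (orange squares) leaves; bars are the recovered SD divided by the square root of 3 arrays, and the dotted line is the background level of log2 2. In the meristem miR396c/d stood at 3.70 in control and 6.70 in chilled leaves, and in the mature zone miR319a/b/c/d-3p stood at 5.34 and 1.59.

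The first chilling comparison asked which miRNAs of the leaf meristem respond to cold nights. In the chilled meristem miR396c/d rose from 3.70 to 6.70 (3.00, SE 0.59, adjusted p = 0.0126). The miR169l-5p level, of a family that targets NF-YA transcription factors, fell from 7.36 to 5.42 (-1.94, SE 0.22, adjusted p = 9.04e-05). At an adjusted p of 0.0491 each, miR408b-5p rose from 4.95 to 6.60 (1.65, SE 0.44), miR1432-5p fell from 6.29 to 4.40 (-1.89, SE 0.47), and 11 identical miR395 3p members, of a family that targets ATP sulfurylases and a sulfate transporter, fell from 9.51 to 8.30 (-1.21, SE 0.35). At that same adjusted p, miR166m-5p fell from 8.33 to 7.33 (-1.0, SE 0.26), miR166c-5p from 8.37 to 7.40 (-0.97, SE 0.26), and miR159f-5p rose from 1.26 to 2.09 (0.83, SE 0.23), with its control level at background. The miR398a/b-3p profile (1.49 in control and 2.75 in chilled leaves, adjusted p = 0.0522) and miR160f-3p (8.42 in control and 7.68 in chilled leaves, adjusted p = 0.0680) did not pass.

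In the meristem 19 probe sets passed, 4 higher and 15 lower under chilling, and these form 8 distinct profiles. At an unadjusted p under 0.05 there were 34. The 11 identical miR395 members carry most of this count, and with 1 probe set per profile 2 profiles passed, 1 higher and 1 lower. The split was 12 higher and 8 lower with quantile normalization and 2 and 1 with median subtraction. The count was 4 without moderation or with a trended robust prior, 9 with the Tukey test, and 1, lower under chilling, with 16 residual degrees of freedom or with an enlarged recovered SD. The fall of miR169l-5p passed under each of its 12 alternatives, and the rise of miR396c/d under 10 of 12. Of the 8 profiles called, 4 also differed between the control mature and elongation zone, a comparison that shares no group with this one, against 79 of all 147 profiles, and 3 of the 4 differed in the same direction.

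Among the fixed lists, the copper, laccase and oxidative stress list stood apart as higher in the chilled meristem by cameraPR (median difference 1.36, adjusted p = 0.00119, and 0.0186 with the correlation of 0.1). Its members belong to families that target copper proteins such as laccases, plantacyanins and copper/zinc superoxide dismutases. Of its 10 members miR408b-5p, a 5p arm, rose and 9 did not pass over all probe sets, among them the 3p profiles of miR398 and miR408. Adjusted over the list alone 5 rose. The miR528a/b-5p profile differed by 0.59 (SE 0.20, adjusted p = 0.0870) and miR398a-5p by 2.96 (SE 1.29, adjusted p = 0.271). Of the sulfate and phosphate list 11 of 34 fell, all of them the identical miR395 members, and 12 fell adjusted over the list alone. Of the growth list 3 of 99 rose and 2 fell, against 2 and 0 adjusted over the list alone. Of the stress factors 1 of 21 fell, with 1 adjusted over the list alone. None of the 44 auxin members, 4 small RNA machinery members or 15 triggers of phased small RNAs passed under limma or adjusted over the list alone, and 3, 0 and 0 had an unadjusted p under 0.05. As families, miR398 (adjusted p = 0.0274), miR396 (0.0332) and miR159 (0.0364) stood apart as higher by cameraPR. The families miR160, measured by 3p arms only (0.0115), and miR395 (0.0332) stood apart as lower. With the correlation of 0.1 the adjusted p was 0.0487 for miR160, 0.0539 for miR398 and 0.125 for the other 3 families. With quantile normalization none of these 5 families stood apart by cameraPR (adjusted p from 0.0783 to 0.203), and with median subtraction miR160 did (0.00446) and the other 4 did not (0.0575 to 0.0627).

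In the elongation zone the same comparison gave few calls. The miR167e-3p level rose from 2.83 to 4.84 (2.01, SE 0.42, adjusted p = 0.0325), and miR169l-5p fell from 7.73 to 6.28 (-1.45, SE 0.22, adjusted p = 0.00252). Among those that did not pass, miR398a/b-3p stood at 2.14 and 3.59 (1.45, SE 0.38, adjusted p = 0.0576), miR408b-5p at 8.06 and 9.55 (1.49, SE 0.44, adjusted p = 0.0839), miR156i-3p at 2.44 and 3.44 (1.0, adjusted p = 0.0576) and miR166n-5p at 6.91 and 5.99 (-0.92, adjusted p = 0.0786). These 2 calls stood beside 35 probe sets with an unadjusted p under 0.05. The count was 1 (lower) with quantile normalization, with 16 residual degrees of freedom or with the enlarged SD, 4 (3 higher, 1 lower) with median subtraction or 1 probe set per profile, and 5 without moderation. It was 9 by unadjusted p with a 2-fold minimum, 10 with a trended robust prior, 11 with joint adjustment and 13 with the Tukey test. Of the 2 profiles called, 1 also differed between the control mature zone and meristem, as did 79 of all 147 profiles.

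The copper list again stood apart as higher in the elongation zone (median difference 1.45, adjusted p = 0.0462), and its adjusted p was 0.222 with the correlation of 0.1 and 0.0527 with median subtraction. None of its 10 members passed over all probe sets under limma, 5 had an unadjusted p under 0.05, and 5 rose adjusted over the list alone. Of the auxin list 1 of 44 rose, miR167e-3p, and of the stress factors 1 of 21 fell, miR169l-5p, and each did so adjusted over the list alone. None of the 99 growth members passed under limma, with 9 at an unadjusted p under 0.05 and 3 higher adjusted over the list alone. None of the 34 sulfate and phosphate, 4 small RNA machinery or 15 phased small RNA trigger members passed under limma or adjusted over the list alone, with 8, 0 and 1 at an unadjusted p under 0.05.

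The mature zone had the most calls under chilling of the 3 zones. The miR319a/b/c/d-3p profile fell from 5.34 to 1.59 (-3.75, SE 0.73, adjusted p = 0.00222), miR166h-5p from 4.61 to 1.48 (-3.13, SE 0.36, adjusted p = 0.000141), miR159e-3p, of a family that targets GAMYB factors, from 4.56 to 1.53 (-3.03, SE 0.45, adjusted p = 0.000367), and miR172a/b/c/d from 4.41 to 1.78 (-2.63, SE 0.59, adjusted p = 0.00591). The miR390a/b-3p profile fell from 4.80 to 1.85 (-2.95, SE 0.46, adjusted p = 0.000367); the 5p arm of miR390 guides the cleavage of TAS3 transcripts. The chilled levels of these 5 profiles are at background. The miR169m-3p level fell from 5.27 to 2.01 (-3.26, SE 0.43, adjusted p = 0.000193), and miR166b/d-5p fell from 6.79 to 3.71 (-3.08, SE 0.48, adjusted p = 0.000367).

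Among the miRNAs higher in the chilled mature zone, the miR398a-5p level rose from background at 1.24 to 6.78 (5.54, SE 1.29, adjusted p = 0.00665). The miR408b-5p level rose from 6.84 to 8.76 (1.92, SE 0.44, adjusted p = 0.00591), and miR528a/b-5p rose from 11.39 to 12.26 (0.87, SE 0.20, adjusted p = 0.00591). The miR399a/c/h-3p profile, of a family that targets the PHO2 regulator of phosphate uptake, rose from 5.61 to 7.20 (1.59, SE 0.22, adjusted p = 0.000193), while miR399d-3p of the same family fell from 3.83 to 1.46 (-2.37, SE 0.43, adjusted p = 0.00135), a fall that became 0.04 with median subtraction. The miR827-5p level, of a family that targets SPX domain genes, rose from 1.84 to 2.68 (0.84, SE 0.19, adjusted p = 0.00591), with its control level at background. The miR408a and miR408b-3p profile stood at 6.79 and 8.87 (2.08, SE 0.68, adjusted p = 0.0593) and did not pass.

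In the mature zone 32 probe sets passed, 10 higher and 22 lower under chilling, which form 21 profiles, 2 of them at background in both groups. At an unadjusted p under 0.05 there were 46. Quantile normalization gave 50, with 28 higher and 22 lower. Median subtraction gave 204, all higher, because it subtracts 2.18 in the chilled and 4.59 in the control mature zone. These medians count identical probe sets separately, and over the distinct profiles they were 1.55 and 1.68. The split of higher and lower depends on the scaling, while quantile normalization turned 0 of the 21 called profiles. Of the 14 profiles that fell, miR399d-3p, miR159g-3p, miR166g-5p, miR169l-5p, miR160d-3p (-1.04, SE 0.33, adjusted p = 0.0483) and miR169d (-0.83, SE 0.24, adjusted p = 0.0361) were above 0 after median subtraction. Of the 21 profiles called, 6 also differed between the control elongation zone and meristem, a comparison that shares no group with this one, against 53 of all 147 profiles, and 5 of the 6 differed in the same direction.

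Of the growth list 14 of 99 members (7 of 60 distinct profiles) fell in the chilled mature zone and 2 rose, with the same numbers of members adjusted over the list alone. Of the 2 that rose, miR171n-5p lay under the background level in every group. Among those that fell, the differences of miR159g-3p (-2.07, SE 0.63) and miR166g-5p (-1.60, SE 0.48) were above 0 with median subtraction. Of the auxin list 4 of 44 fell, against 3 adjusted over the list alone, among them miR160a-3p from 4.95 to 2.36 (-2.59, SE 0.59, adjusted p = 0.00591) and miR160d-3p, which was above 0 with median subtraction. Of the copper list 4 of 10 rose, all of them 5p arms, against 6 adjusted over the list alone. The list did not stand apart by cameraPR (adjusted p = 0.0666, and 0.324 with the correlation of 0.1). Of the sulfate and phosphate list 4 of 34 rose and 1 fell, miR399d-3p, with the same numbers adjusted over the list alone. Of the stress factors 3 of 21 fell, also adjusted over the list alone, all of the miR169 family, among them miR169l-5p from 7.64 to 6.37 (-1.27, SE 0.22, adjusted p = 0.00092), whose difference was 1.14 with median subtraction, and miR169d, which was also above 0 there. None of the 4 small RNA machinery or 15 phased small RNA trigger members passed under limma or adjusted over the list alone, with 0 and 3 at an unadjusted p under 0.05. No list stood apart by cameraPR in this zone.

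**Figure D2:**
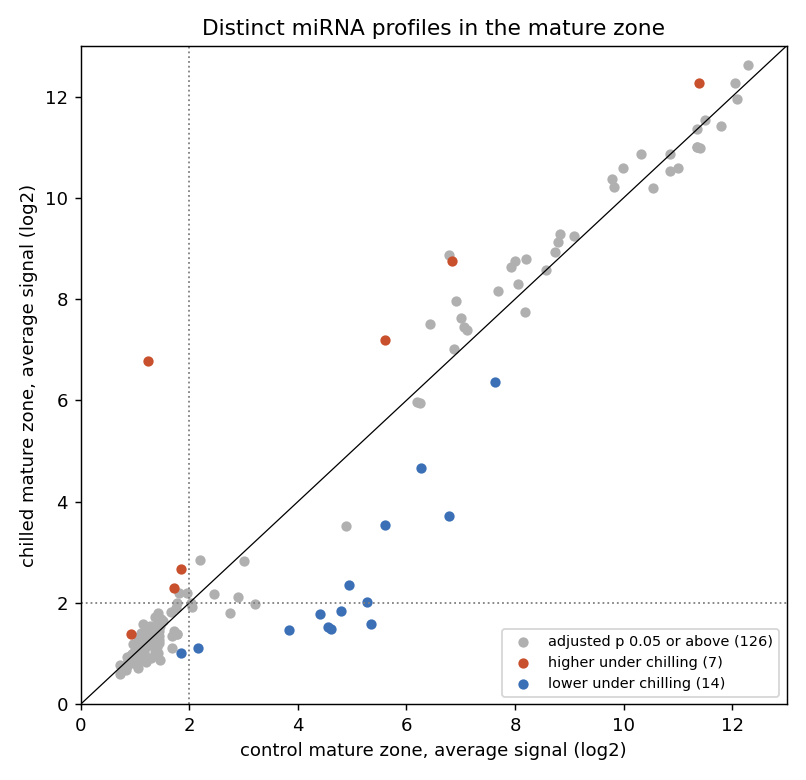
Average log2 signal of the 147 distinct profiles in the control (x axis) and chilled (y axis) mature zone; orange points are the 7 profiles higher and blue points the 14 lower under chilling at an adjusted p under 0.05, grey points did not pass, the line marks equal levels and the dotted lines the background level of log2 2. The profile at 1.24 in control and 6.78 in chilled leaves is miR398a-5p, and that at 5.34 and 1.59 is miR319a/b/c/d-3p.

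Averaged over the zones with equal weight, chilling raised miR408b-5p by 1.69 (SE 0.25, adjusted p = 0.000426), miR528a/b-5p by 0.68 (SE 0.11, adjusted p = 0.000847), miR398a-5p by 3.66 (SE 0.75, adjusted p = 0.00457) and miR399a/c/h-3p by 0.89 (SE 0.13, adjusted p = 0.000341). It lowered miR169l-5p (-1.55, SE 0.13, adjusted p = 1.54e-06), miR169m-3p (-1.71, SE 0.25, adjusted p = 0.000344) and miR319a/b/c/d-3p (-1.71, SE 0.42, adjusted p = 0.0119). The miR169l-5p level was lower in each of the 3 zones, past the threshold in each. Its mature difference kept its direction and passed under 11 of 12 alternatives. It turned with median subtraction, which moved all differences in that zone up by the same amount. Among the profiles called in single zones, miR408b-5p was called higher in the meristem and the mature zone. Its meristem call held under 6 of 12 alternatives and its mature call under 12 of 12. Of the 147 profiles 20 had a positive and 25 a negative difference in 3 of 3 zones.

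**Figure D3:**
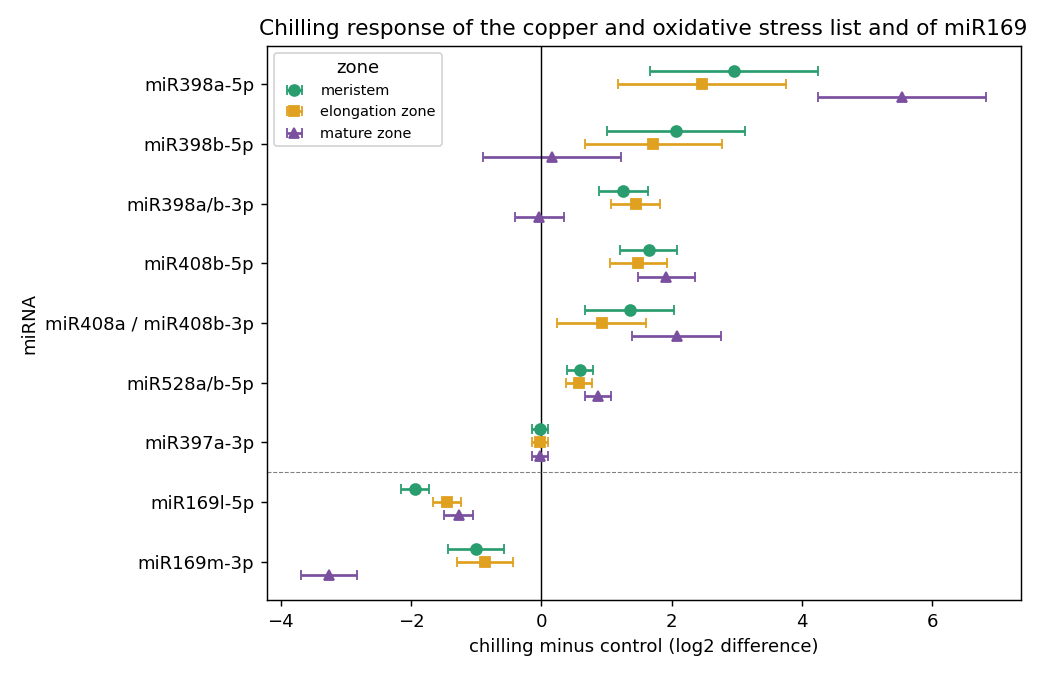
Log2 difference of chilled minus control average signal in the meristem (green circles), elongation zone (yellow squares) and mature zone (purple triangles) for the 7 profiles of the copper, laccase and oxidative stress list and for 2 miR169 profiles; bars are the recovered SE of the difference. The differences of miR408b-5p were 1.65, 1.49 and 1.92 and those of miR169l-5p were -1.94, -1.45 and -1.27, the last of which turned with median subtraction.

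For the average 42 probe sets passed, 14 higher and 28 lower, against 63 at an unadjusted p under 0.05. The split was 28 higher and 19 lower with quantile normalization and 167 and 2 with median subtraction, and the count fell to 14 with 16 residual degrees of freedom, to 13 with the enlarged SD and to 17 by unadjusted p with a 2-fold minimum. Of the copper list 8 of 10 members rose, also adjusted over the list alone, and the list stood apart by cameraPR (median difference 1.32, adjusted p = 0.000359, and 0.00791 with the correlation of 0.1). That list call ended with quantile normalization (adjusted p = 0.0670) and with median subtraction (adjusted p = 0.375), with the list still higher in both. Its other rises were the profiles miR408a and miR408b-3p (1.46, adjusted p = 0.0214) and miR398a/b-3p (0.89, adjusted p = 0.0119), of which the latter stood at background in the mature zone in both treatments (0.99 and 0.96). Of the sulfate and phosphate list 4 of 34 rose and 12 fell, also adjusted over the list alone, the 12 being miR395 members whose average differences (-0.62 for the 11 identical ones, -0.65 for miR395o-3p) were above 0 with median subtraction. Of the growth list 10 of 99 fell, also adjusted over the list alone, and of these miR166a-5p, miR166c-5p and miR166m-5p were above 0 with median subtraction. Of the auxin list 2 of 44 rose and 4 fell, among them miR160d-3p, which was above 0 with median subtraction, against 0 and 3 adjusted over the list alone, and of the stress factors 2 of 21 fell, also adjusted over the list alone. None of the 4 small RNA machinery or 15 phased small RNA trigger members passed under limma or adjusted over the list alone, and none had an unadjusted p under 0.05. Of the families, miR398 stood apart as higher (adjusted p = 0.0241) and miR160 and miR166 as lower (0.0208 each), with 0.0703, 0.0703 and 0.169 with the correlation of 0.1. The miR166 members called lower on average were all 5p arms. In the chilled mature zone, miR166 profiles above background in the control had a mean change of -2.60 for the 5p arm and 0.555 for the 3p arm. The 5p mean is that of miR166b/d-5p, miR166h-5p and miR166g-5p, which were already called lower in that zone. The arms were not tested against each other. With median subtraction miR160 and miR166 still stood apart as lower than the other miRNAs (adjusted p = 0.0480 each), while their median differences moved from -0.77 to 0.09 and from -0.27 to 0.58, and miR398 did not stand apart (0.762). With quantile normalization the adjusted p was 0.0200 for miR166, 0.107 for miR160 and 0.183 for miR398. Over all 161 list tests, 47 had a median, mean and test that differed in sign, and 0 of those were called.

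The zones of chilled leaves were compared in the same way as those of the controls. Here miR396c/d stood at 6.70 in the meristem and miR166n-5p at 5.99 in the elongation zone. Between the elongation zone and the meristem 118 probe sets passed, 84 higher and 34 lower (65 and 61 with quantile normalization). Between the mature and the elongation zone 148 passed, 23 higher and 125 lower (52 and 39 with quantile normalization, 186 and 8 with median subtraction). Without miRNAs at background in every group 3 of those were higher and 109 lower, and without the lowest 25% of probe sets 0 were higher and 102 lower by limma. Between the mature zone and the meristem 177 passed, 75 higher and 102 lower (91 and 86 with quantile normalization, 188 and 20 with median subtraction). Of the 125 falls from elongation to mature zone, 23 were no longer below 0 with quantile normalization and 103 with median subtraction. Of the 102 falls from meristem to mature zone these numbers were 6 and 75. Median subtraction moved all differences of a contrast alike. It subtracts 2.18 in the chilled mature zone, 5.85 in the elongation zone and 5.865 in the meristem. These medians count identical probe sets separately, and over the distinct profiles they were 1.55, 3.78 and 3.23. The counts with median subtraction therefore reflect the size of that shift and do not test single falls. Of the 84 rises from meristem to elongation zone 4 were below 0 with quantile normalization.

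Whether the chilling effect itself differed between zones was tested by the interaction. The effect on miR159e-3p was 0.64 in the meristem, 0.19 in the elongation zone and -3.03 in the mature zone (F test, adjusted p = 0.0132). The profile miR172a/b/c/d had effects of 1.18, 0.30 and -2.63 (adjusted p = 0.0227), and miR396c/d had effects of 3.00, -0.05 and -0.39 (adjusted p = 0.0301). In all 16 probe sets, or 10 profiles, passed the F test, with 38 probe sets at an unadjusted p under 0.05. The count was 3 with 16 residual degrees of freedom and 0 with the enlarged SD, 39 with quantile normalization and 194 with median subtraction. By pairs of zones, 19 probe sets differed between mature zone and meristem (5 higher, 14 lower), 5 between mature and elongation zone (1 higher, 4 lower) and 0 between elongation zone and meristem by limma, where 17 had an unadjusted p under 0.05.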

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

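All tests of explanations in this part were chosen only after the results were seen, except the test of elongation zone tissue behind miR396c/d, whose outcome was set down before. The 16 probe sets (10 profiles) whose chilling effect differed between zones drew attention by the F test of that difference. Effects are given for the meristem, elongation zone and mature zone in this order, with the adjusted p of the limma F test. Profiles with a fall in the mature zone were miR159e-3p (0.64, 0.19, -3.03; 0.0132), miR166h-5p (-0.49, -0.38, -3.13; 0.0132), miR399d-3p (0.56, 0.80, -2.37; 0.0132), miR166b/d-5p (0.35, -0.80, -3.08; 0.0227), miR390a/b-3p (0.20, -1.11, -2.95; 0.0227), miR172a/b/c/d (1.18, 0.30, -2.63; 0.0227) and miR169m-3p (-1.0, -0.86, -3.26; 0.0304). The others were miR160f-3p (-0.74, -0.75, 0.61; 0.0227), miR167g-3p (-0.08, 0.93, -0.79; 0.0301), which lies near background, and miR396c/d (3.0, -0.05, -0.39; 0.0301). With an enlarged recovered SD 0 of them passed the limma F test, where 38 had an unadjusted p under 0.05 with the SD as recovered.

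The first pattern is the loss of signal of miRNAs of middling level in the chilled mature zone. A scale that bends with the level on the chilled mature arrays would move miRNAs of the same control level alike. Above a control level of log2 5.5, 2 pairs of the same control level were called in opposite directions: miR408b-5p rose while miR166b/d-5p fell (difference of changes 5.0, SE 0.65), and miR399a/c/h-3p rose while miR159g-3p fell (3.66, SE 0.67). This argues against such a scale for these pairs only, which were picked from 7 called profiles after the result was seen. The call of miR159g-3p was kept under 5 of 12 alternatives. Between 3.5 and 5.5 such a scale stays open, since 8 of 9 profiles fell by more than 2 SE and 0 rose. A chilled piece cut farther along the leaf also stays open. By more than 2 SE, 8 of the 14 profiles that fell (57.1%), and 2 of the 7 that rose, were already lower in the control mature than elongation zone. Over all profiles, 68 of 147 were called lower there, by adjusted p rather than 2 SE. These shares decide neither way, and they use the control mature average in both comparisons. Whether the arm with the lower signal falls more could not be told either, with 5 of 8 families (two-sided exact sign test, p = 0.727), and the biological explanation, a response to cold nights in mature tissue, remains untested beside them.

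The second pattern is the rise of miR396c/d in the chilled meristem. Elongation zone tissue in the chilled meristem piece may explain it, since 3.6% of such tissue would give the rise. The 11 other miRNAs at least 4-fold higher in the control elongation zone than in the meristem had a weighted mean change of 0.26 (SE 0.15), against 0.38 predicted from that share. The control meristem average enters both comparisons. The weighted mean change lies within 2 SE of the prediction and also of 0, so tissue and a response of the meristem to cold cannot be told apart. The small share needed keeps this open. The 11 include miR408b-5p, called higher in the chilled mature zone too, and the miR408a profile, called higher on average over the zones. Their rise may be a response to cold rather than a sign of tissue, and the mean without them was not computed.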

How the results depend on the processing

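Leaving out the lowest 25% of probe sets, quantile normalization, median subtraction, the trended prior, the threshold, joint adjustment and 1 probe set per profile were planned before the data were examined; the other alternatives were added after the data were seen. No paired analysis was possible because the table holds group averages and no single arrays. For the same reason the replicate blocks, fits of only the groups compared, leaving out arrays, an estimated correlation and other splits of the samples were not run, so whether another grouping of the arrays would give as many calls is not known. Family means were not run, and a pseudocount does not apply to log2 values. Of 1957 values of 170 named differences under alternatives, 1657 kept direction and side of the threshold, 238 no longer passed, 30 passed newly and 32 reversed. Signal over background limits the rest: 41 of 147 profiles lie under log2 2 in every group. The cause of the following changes was not tested, apart from what an alternative does by construction.

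With quantile normalization the counts were 1 in the chilled elongation zone, 50 in the chilled mature zone, 72 and 91 for mature against elongation zone in control and chilled leaves, 39 for the interaction and 6 chilling list calls, against 11. Of the called profiles, it turned, or brought to 0, 17 of 79 for mature against elongation zone and 7 of 79 for mature zone against meristem in control leaves, and 17 of 105 and 5 of 106 in chilled leaves, besides 4 of 66 for chilled elongation zone against meristem. Of the named differences it reversed, for control mature against elongation zone, miR168a-3p (0.117), miR162-5p (0.05), miR162-3p (0.527), miR169m-5p (0.217) and miR169d (1.44), and, for mature zone against meristem, miR162-5p (0.347) and miR169m-5p (0.219). With median subtraction they were 3 in the chilled meristem, 4 in the elongation zone, 204 in the mature zone, 169 on average, 194 for the interaction and 5 list calls. It reversed, in the mature zone, miR399d-3p (0.035), miR159g-3p (0.335), miR166g-5p (0.805), miR169l-5p (1.14), miR160d-3p (1.37) and miR169d (1.58), and on average miR160d-3p (0.033), miR166c-5p (0.14), miR395o-3p (0.21), the miR395b-3p profile (0.23), miR166a-5p and miR166m-5p (0.25 each). Of the called profiles, it turned 24 and 21 of 79 for control mature zone against elongation zone and against meristem. In chilled leaves it turned 68 of 105 and 52 of 106. Median subtraction moved all differences of a contrast alike, so these turns reflect the size of that shift. Of the named differences it reversed, for control mature against elongation zone, miR398a/b-3p (0.135), miR408b-5p (0.065), miR399g-5p (0.595), miR399f-3p (0.605), miR162-3p (0.185), miR169d (0.275) and miR2275b-5p (0.045). For control mature zone against meristem it reversed, among those named, miR399g-5p (0.675), miR399g-3p (0.835), miR168a-3p (0.435), miR169m-5p (0.205), miR482-5p (0.125) and miR2275a-5p (0.265). In the mature zone the median probe set sits between background and expressed miRNAs.

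The trended robust prior gave 4 calls in the chilled meristem, 10 in the elongation zone and 7 list calls between zones, against 4. An unadjusted p with a 2-fold minimum gave 9 in the elongation zone and 17 on average, joint adjustment 11 in the elongation zone, and 1 probe set per profile 2 in the meristem and 4 in the elongation zone. Without moderation there were 4 and 5 in these zones. The Tukey test gave 9 and 13 there, 56 for elongation zone against meristem and 74 for mature against elongation zone in control leaves. With 16 residual degrees of freedom there were 1 and 1, 14 on average and 3 for the interaction. With the enlarged SD there were 1 and 1, 13 on average, 0 for the limma interaction test (38 at an unadjusted p under 0.05 as reported), 52 and 70 for these control zone contrasts and 98 for mature against elongation zone in chilled leaves. Without miRNAs at background in every group 5 chilling list calls were left, and with the correlation of 0.1 there were 3 under chilling and 1 between zones.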

Other observations

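The miR168a-3p level, whose family targets ARGONAUTE1, stood at 9.55, 9.99 and 8.57 in the control meristem, elongation and mature zone and at 9.56, 9.62 and 8.57 in the chilled ones. The miR2118 members, known as triggers of phased small RNAs in reproductive organs, lay at background in all 6 groups, such as miR2118b between 0.75 and 1.19. Of miR2275, the 5p arm of miR2275a reached 3.44 in the control and 3.79 in the chilled elongation zone. In the chilled mature zone miR398a-5p stood at 6.78, against 1.24 in the control, while miR398b-5p (1.54 against 1.38) and miR398a/b-3p (0.96 against 0.99) were at background in both; the changes of these members were not tested against each other.

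The third pattern concerns miRNAs at background, and its tests were chosen after the result was seen. The authors' deposited table holds only probe sets under some p limit, and 204 of all 228 probe sets had an FDR under 0.05. Background probe sets that failed the ANOVA are therefore not seen, and how often such probe sets pass is not known. Of the 41 profiles under log2 2 in every group, 29 had an FDR under 0.05 in the authors' deposited table, while their 6 averages spanned a median of 0.56 and at most 1.00. A common shift of background between the arrays of the zones may make such small differences pass, but it would move these profiles one way. From the control meristem to the control mature zone 21 of them were higher and 19 lower, with 5 called higher and 5 called lower. So 46.3% moved in the smaller direction, which argues against one common shift between these zones as the cause. From meristem to elongation zone the calls were one-sided, with 3 higher and 0 lower in control leaves and 6 and 0 in chilled leaves. Over all 41 profiles 25 were higher and 15 lower in control leaves, and 26 and 14 in chilled leaves. A shift of the elongation zone arrays therefore stays open for these calls. The chilled mature zone, with the highest median of these profiles (1.26, against 1.06 in the control mature zone), gave no single direction either: 25 were higher and 15 lower than in the control mature zone, and against the chilled elongation zone 15 passed the threshold as higher and 15 as lower. In the authors' deposited table the ratio of FDR to p at the smallest p corresponds to 36207 features, and if Benjamini-Hochberg adjustment was used, 54.2% of these would lie at or under the largest p listed (4.1%). Shifts that depend on the probe sequence were not tested, nor was a biological explanation.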
